A study of Mus musculus with 8 samples.

How the data were processed

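Gene expression was measured in mouse CJ7 embryonic stem cells and in Ezh2-/-, Eed-/- and Jarid2-/- embryonic stem cells, with 2 arrays per group and 8 arrays in all. Per the labels, cells were grown in medium with 15% fetal calf serum and 1000 U/ml of leukemia inhibitory factor, a cytokine that keeps stem cells undifferentiated. Total RNA was taken with Trizol, labelled as biotin cRNA and hybridized to Affymetrix Mouse430A_2 arrays. The deposited value table gives intensity per probe set on a linear scale, with a lowest value of 1 and array medians between 323.6 and 352.4. The normalization behind the deposited intensity is not named for that table. A dChip signal table that accompanies the series states a model-based expression with an outlier check and without log transformation. The 12 columns of that dChip table match no sample label, so none could be given to a sample and its values were not used here. This departs from the plan made before the data were examined, which named the dChip table as the input. A filter on present calls was planned as well and could not be run, because no detection calls are given.

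The 64 control probe sets were left out and 22626 were tested. Values below 1 were set to 1, 16 was added and log2 was taken, with no further normalization between arrays and no filter on dim probe sets. Gene symbols came from the platform table: 20380 probe sets had 1 symbol, 691 had several and 1555 had none, and no symbol changed among the 20351 looked up by Entrez identifier. Probe sets with several symbols were tested and not named. Genes were placed on chromosomes by the assembly GRCm38.p6. Chromosome medians were taken over genes with a mean signal above 500 and camera was run over all genes of a chromosome.

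Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with a mean per genotype over all 8 arrays, so that the 4 groups shared 1 estimate of spread with 4 residual and 5.02 prior degrees of freedom. All p-values of single genes are two-sided limma values adjusted by Benjamini and Hochberg over all probe sets tested within a comparison, and a change was called at an adjusted p under 0.05. Each mutant was compared with wild type and with each other mutant, 6 comparisons in all. The replicate number was not used as a block, since the labels do not say that it marks a shared culture or day. Replicate deviations correlated by 0.411 between wild type and Jarid2-/-, by 0.244 between Eed-/- and Jarid2-/-, and by 0.008 to 0.05 between the other groups. A shared replicate effect in the first 2 pairs is therefore not excluded, and the block was run as an alternative. For genes with several probe sets, the brightest over the 8 arrays was used to stand for the gene, which gave 12393 genes.

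There were 20 gene lists fixed before the data were examined: PRC2 subunits, PRC1 subunits, maternally expressed RNAs, paternally expressed genes and neighbouring genes of the Dlk1-Dio3 region, other imprinted genes, DNA methylation machinery, Hox genes, pluripotency genes, primitive and visceral endoderm markers, primitive streak and mesoderm markers, neural and ectoderm regulators, trophectoderm markers, germline genes, genes of the 2-cell-like state, cell cycle inhibitors and p53 targets, fibroblast and feeder cell markers, stress and immediate early genes, ribosomal protein genes, and Y-linked genes with Xist. Some genes, such as Zfp42, Dppa3, Cdkn1c and Dcn, are on 2 lists. Members were counted as higher, lower or not past the threshold over all probe sets and over the list alone. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The region's lists of maternally and paternally expressed members were too small for camera. No list called at the preset correlation against wild type held with an estimated correlation.

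Genes were named by rules set before the data were examined. These were the 3 targeted genes and the measured genes of the Dlk1-Dio3 region with all probe sets. To these came the 8 largest increases and decreases in each mutant and the 5 largest in each direction between mutants, among genes past the threshold. Both arrays of the first group had to lie outside the range of the second group, and the brighter mean above 336.7. Up to 4 list members with the smallest p per comparison, and the 8 largest shared changes per direction, were named too. The likeness of mutants was measured across genes beside 100 simulations with unchanged groups against the same wild type arrays.

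The method was tested on simulated data with 22626 probe sets: limma recovered 60% of 50 changes of 1.5-fold, 98% of 100 changes of 2-fold and 100% of 50 changes of 4-fold, and 17 of 195 calls were of unchanged probe sets. In a separate simulation without these changes camera called 3 of 3 lists of 20 genes shifted by log2 0.5 and 0 of 3 unshifted lists. Its genes were drawn independently, so it does not test calls of lists whose genes vary together. Alternatives were pseudocounts of 1 and 64, quantile normalization, equal array medians, a filter at the 40th percentile of brightness that kept 13575 probe sets, no intensity trend, array weights, the replicate block, a fit of the 4 arrays compared, a 2-fold limit, the mean over the probe sets of a gene, an estimated correlation, and leaving out each array in turn. Fits without the 2 arrays labelled Jarid2-/-, a separate wild type array for each mutant of a pair, and all alternatives of the chromosome medians were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.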

Results

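The deposited series measured messenger RNA in mouse embryonic stem cells of the CJ7 line, a line used for gene targeting, and in cells lacking a component of Polycomb repressive complex 2 (PRC2). PRC2 is a chromatin complex that methylates histone H3 and keeps developmental genes repressed. The 4 groups were wild type, Ezh2-/-, Eed-/- and Jarid2-/-, with 2 arrays each and 8 arrays in all. EZH2 is a methyltransferase subunit, EED binds the methylated histone, and JARID2 helps to bring the complex to chromatin. The arrays carried 22626 probe sets besides controls, and the median signal per array lay between 323.6 and 352.4, where negative control probe sets for a bacterial transcript read 23.76 to 147.91. Replicate arrays correlated across probe sets with Pearson's r between 0.9938 and 0.9975, although probe sets are not independent replicates. The small number of arrays limits the precision of every value. The labels do not say whether the 2 arrays of a group came from separate cultures, so each p measures only the spread between these arrays. Genotype and cell line coincide, so a difference between groups can come from the line as well as from the missing subunit. Values below are deposited signal intensities given as mean ± SD with n = 2 arrays per group, and changes are log2 differences with the standard error (SE) of the linear model. Where a group read within or below the range of the negative controls, background sets part of the value, so the log2 difference is not exact.

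The first question was whether each mutant showed the loss it was labelled with. Ezh2 signal (1 probe set, gene on chromosome 6) was 4800 ± 282 in wild type and 696 ± 65.4 in Ezh2-/-, a 6.77-fold lower value (log2 -2.76, SE 0.09, adjusted p = 2.6e-07). Eed signal at its bright probe set was 10300 ± 856 in wild type and 3610 ± 38.7 in Eed-/-, 2.83-fold lower (log2 -1.5, SE 0.07, adjusted p = 9.6e-06). Ezh2 was at 5010 ± 54.3 in Eed-/- (log2 0.06, adjusted p = 0.66). Jarid2 was read by 3 probe sets, and none was lower in the arrays labelled Jarid2-/-. The brightest read 9470 ± 1070 against 7950 ± 33.2 in wild type (log2 0.25, SE 0.08, adjusted p = 0.052), the next 8240 ± 730 against 7020 ± 152 (log2 0.23, adjusted p = 0.038) and the dimmest 4950 ± 747 against 4340 ± 318 (log2 0.18, adjusted p = 0.25). The value of the brightest probe set passed the threshold when quantile normalization (0.272) or equal array medians (0.315) were applied, with the replicate number as a block (0.246), and without Jarid2-/- replicate 2 (0.361). Probe sets outside the deleted part of a gene cannot show its loss, and the deleted part is not given in the sources used here. The Jarid2 signal is therefore no test of the label, and these arrays are called the arrays labelled Jarid2-/-. They had less Ezh2 signal than wild type, 3020 ± 138 (log2 -0.66, SE 0.09, adjusted p = 0.0015), which is 63% of the wild type level. The 40 bright genes nearest to Ezh2 on chromosome 6 were lower in these arrays too, with a median of -0.504, a comparison chosen after the chromosome medians were seen.

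**Figure D1:**
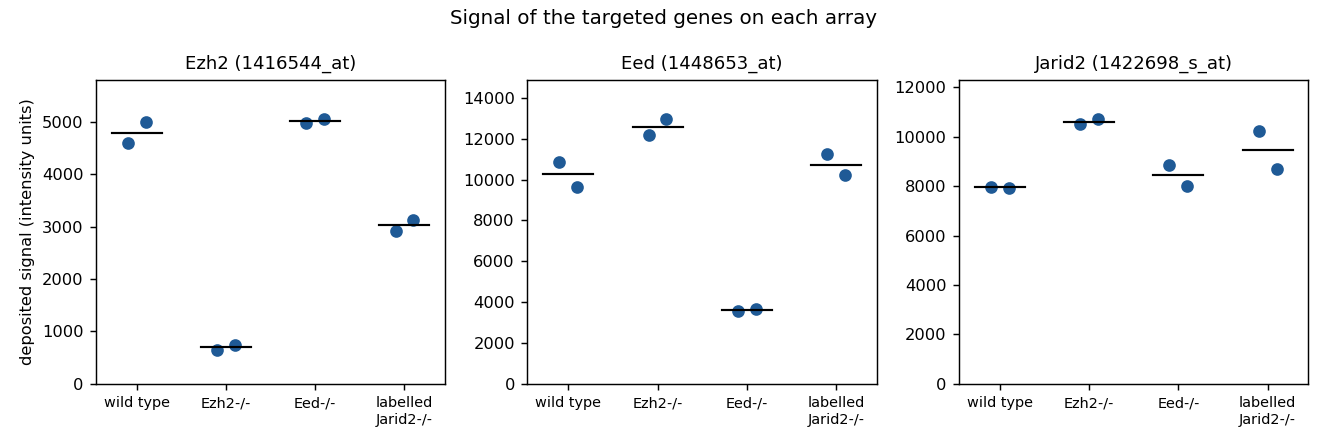
Signal of Ezh2, Eed and Jarid2 (brightest probe set of each gene, linear intensity on the vertical axis) in the 8 arrays of the 4 genotypes; points are arrays and bars are means of 2 arrays. Ezh2 fell to 696 in Ezh2-/- and Eed to 3610 in Eed-/-, while Jarid2 was at 9470 in the arrays labelled Jarid2-/- and at 7950 in wild type.

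The locus named in the series title is the imprinted Dlk1-Dio3 region of chromosome 12. Its maternal copy makes the long non-coding RNAs Meg3 (also called Gtl2), Rian and Mirg. The comparison asks how their level differs between wild type and each PRC2 mutant. Meg3 signal at its brightest probe set was 7810 ± 1050 in wild type and 117 ± 10.2 in Ezh2-/- (log2 -5.87, SE 0.14, adjusted p = 4.3e-08), which lies within the range of the negative controls and is at least 52.8-fold lower when set against the highest of them. It was 1340 ± 193 in Eed-/-, 5.78-fold lower (log2 -2.53, adjusted p = 2.4e-05). In the arrays labelled Jarid2-/- it was 810 ± 92.8, 9.46-fold lower (log2 -3.24, adjusted p = 5e-06). Rian, a host of small nucleolar RNAs, went from 1060 ± 31.4 to 48.6 ± 8.08 in Ezh2-/- (log2 -4.06, SE 0.12, adjusted p = 1.4e-07), to 192 ± 15.1 in Eed-/- (log2 -2.37, adjusted p = 1.2e-05) and to 158 ± 13.4 in the arrays labelled Jarid2-/- (log2 -2.63, adjusted p = 5.2e-06). As a share of wild type, Meg3 stood at no more than 1.9%, at 17.1% and at 10.4%, and Rian at no more than 14%, at 18.1% and at 14.9% in the same order, where the upper bounds in Ezh2-/- take the highest negative control as the signal. All 5 Meg3 and all 3 Rian probe sets were lower in every mutant, and each passed the threshold except the dimmest Meg3 probe set in Eed-/- (log2 -0.35, adjusted p = 0.069). Both RNAs were lower in Ezh2-/- than in Eed-/-. The median difference of -2.52 over the pair is not exact, since both Ezh2-/- signals lay within the range of the negative controls. For Rian the Eed-/- signal of 192 was itself not far above the highest control of 147.91. The calls for the brightest probe sets of Meg3 and Rian held under every processing alternative and with each array left out. Markers of fibroblasts were lower as well, and over 8 that were bright in wild type the median was -2.45 in Ezh2-/-, -0.79 in Eed-/- and -2 in the arrays labelled Jarid2-/-, with Col1a2 at -2.74, -2.33 and -2.94. Mirg, Rtl1 and Dio3 were not analysed here.

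Dlk1, a paternally expressed gene of the same region that encodes a Notch-like membrane protein, was dim in wild type at 143 ± 7.13, within the range of the negative controls. It was 112 ± 12 in Ezh2-/- (log2 -0.31, SE 0.12, adjusted p = 0.082) and 168 ± 11.6 in Eed-/- (log2 0.21, adjusted p = 0.24), neither past the threshold. With the replicate number as a block the Ezh2-/- value (-0.312) passed. In the arrays labelled Jarid2-/- Dlk1 was 91.3 ± 10.5 and lower (log2 -0.57, adjusted p = 0.011), a call that ended without wild type replicate 1 (-0.521) or without Jarid2-/- replicate 2 (-0.467). Of 8 measured genes that flank the region, Evl, an actin regulator, rose in Eed-/- from 630 ± 55 to 1090 ± 9.11 (log2 0.78, SE 0.13, adjusted p = 0.0045). Evl was also higher in Ezh2-/- (log2 0.58, adjusted p = 0.01), which ended without Ezh2-/- replicate 1 (0.602) or replicate 2 (0.563). Of these 8 neighbouring genes 1 was higher, 1 lower (Dync1h1, log2 -0.34) and 6 not past the threshold in Ezh2-/-, with the same counts for higher and lower when adjusted over the list alone (set test adjusted p = 0.35, and adjusted p = 0.57 with an estimated correlation). The Dync1h1 call ended without wild type replicate 2 (-0.313) or Ezh2-/- replicate 1 (-0.408) or 2 (-0.28), and with equal array medians or no intensity trend. In Eed-/- 2 were higher and 6 not past, also when adjusted over the list alone (adjusted p = 0.19, and adjusted p = 0.30 with an estimated correlation). The other of the 2, Yy1 (log2 0.23, adjusted p = 0.05), was at the threshold, and its call ended without wild type replicate 2 (0.181), Eed-/- replicate 1 (0.29) or 2 (0.171), or Ezh2-/- replicate 1 or 2 (0.231 for each), and under 6 processing alternatives. In the arrays labelled Jarid2-/- limma placed 0 of 8 past the threshold and 0 at an unadjusted p under 0.05 (adjusted p = 0.31, and adjusted p = 0.48 with an estimated correlation).

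**Figure D2:**
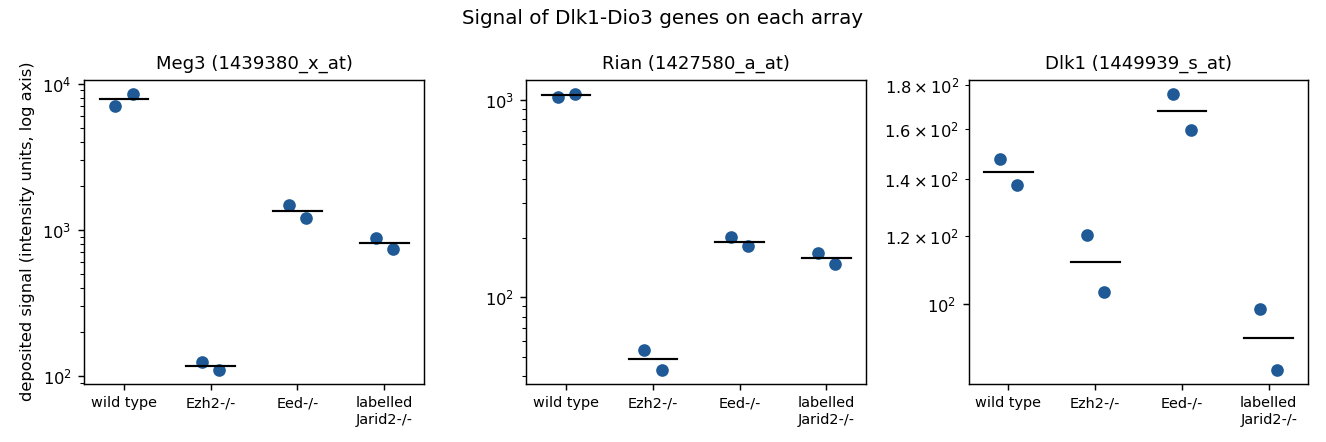
Signal of Meg3, Rian and Dlk1 (brightest probe set of each gene, intensity on a log axis) in the 8 arrays; points are arrays and bars are means of 2 arrays. Meg3 lay at 7810 in wild type and at 117, 1340 and 810 in Ezh2-/-, Eed-/- and the arrays labelled Jarid2-/-, and Dlk1 stayed between 91.3 and 168.

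The comparison of Ezh2-/- with wild type asks how expression differs in embryonic stem cells that lack EZH2, a methyltransferase subunit of PRC2. It cannot separate that loss from other differences between the 2 lines. Olig2 and Olig1, transcription factors of the oligodendrocyte lineage, rose from 30 ± 0.332 to 971 ± 4.45 (log2 4.42, SE 0.09, adjusted p = 3.4e-08) and from 79 ± 30.2 to 1680 ± 71.5 (log2 4.2, SE 0.19, adjusted p = 1.9e-06). Sox7, a regulator of primitive endoderm, rose from 46.7 ± 5.54 to 655 ± 31.6, and the lipoprotein gene Apoa2 rose from 126 ± 1.01 to 1630 ± 19. Zfp42, which encodes the stem cell marker REX1, fell 4.76-fold from 18400 ± 532 to 3850 ± 195 (log2 -2.25, SE 0.07, adjusted p = 2.4e-07). The Y-linked genes Eif2s3y and Uty fell from 1600 ± 42.3 to 16.7 ± 5.14 and from 405 ± 84.1 to 9.57 ± 2.74, below every negative control, which bounds them at no more than 9.3% and 36.5% of wild type when set against the highest control. In Eed-/- these 2 genes stood at 137.3% and 102.7% of wild type, so their low signal was not shared by all PRC2 mutants. The other largest increases were Gm6958 (log2 4.71), 2210409E12Rik (log2 4.19), Tmem267 (log2 4.07) and Rpgrip1 (log2 3.48), where Rpgrip1 had the same sign at 2 of 4 probe sets. The other largest decreases besides Meg3 and Rian were Dpys of pyrimidine breakdown (log2 -5.77), the interferon-induced GTPases Gbp2b (log2 -5.55) and Gbp2 (log2 -4.53), and Fxyd6 (log2 -3.93), all with SE of at most 0.26.

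Of 22626 probe sets tested, 2130 were higher and 3882 lower in Ezh2-/-, 6012 in all at an adjusted p under 0.05, and 278 higher and 584 lower at 2-fold or more. The higher share was 35.4%, against 49.5% after quantile normalization and 51.8% with equal array medians, so the balance of directions depended on the scaling of the arrays. The median over all probe sets was -0.07. The total fell to 2838 without Ezh2-/- replicate 1 and to 2655 without Ezh2-/- replicate 2.

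Genes of the DNA methylation machinery were mostly higher in Ezh2-/-. Of 14 measured, 8 were higher and 6 not past the threshold, 10 were higher when adjusted over the list alone, and the median was 0.36 (adjusted p = 5.4e-06, and adjusted p = 0.20 with an estimated correlation). Dnmt3l, a cofactor of the de novo methyltransferases, rose from 5350 ± 1120 to 13200 ± 231 (log2 1.32, SE 0.14, adjusted p = 0.00029). Dnmt3b, a de novo methyltransferase, rose to 13200 ± 106 from 9740 ± 633 (log2 0.44, adjusted p = 0.00052), with Ehmt2, a histone methyltransferase, at log2 0.78 and the methyl-CpG binding gene Mbd2 at log2 1.07. Pluripotency genes went both ways, with 12 higher, 4 lower and 10 not past of 26, and 13 higher and 6 lower when adjusted over the list alone. Most of the 12 higher calls did not hold with each array left out in turn, while most of the 4 lower calls did. Klf5 rose (log2 1.09, SE 0.07) while Klf2 (log2 -1.3) and Fbxo15 (log2 -1.41) fell with Zfp42. The list median was 0.19 and its mean -0.02, and the set test called it higher (adjusted p = 0.039, and adjusted p = 0.29 with an estimated correlation). That set call ended under quantile normalization, equal array medians, a filter on dim probe sets and the mean over the probe sets of a gene, and without wild type replicate 1 (median 0.156), Ezh2-/- replicate 1 (0.203) or Ezh2-/- replicate 2 (0.205).

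Fibroblast markers were lower in Ezh2-/-, with 13 of 22 lower and 9 not past, 14 lower when adjusted over the list alone, and a median of -0.68 (adjusted p = 1e-04, and adjusted p = 0.20 with an estimated correlation). Tagln, a smooth muscle actin-binding gene, fell from 4960 ± 1980 to 357 ± 63.7 (log2 -3.69, SE 0.32) and the collagen gene Col1a1 from 490 ± 82.1 to 24.5 ± 5.87 (log2 -3.64, SE 0.25). Trophectoderm markers included the keratins Krt8 (10000 ± 3360 to 1120 ± 346, log2 -3.14, SE 0.4), Krt18 (log2 -2.91) and Krt19 (log2 -3.8), and the regulator Tfap2c fell as well (log2 -1.5). Of 14 on that list 6 were lower and 8 not past, with 1 higher and 6 lower when adjusted over the list alone and a median of -0.33 (adjusted p = 0.039, and adjusted p = 0.57 with an estimated correlation). The trophectoderm call ended with the replicate number as a block, and without wild type replicate 1 (-0.436) or Ezh2-/- replicate 2 (-0.28).

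The lists of PRC2 subunits, PRC1 subunits and Hox genes did not pass as sets in Ezh2-/-. The 12 PRC2 subunits gave 3 higher, 4 lower and 5 not past, the same when adjusted over the list alone for higher and lower (adjusted p = 0.79, and adjusted p = 0.80 with an estimated correlation). The 14 PRC1 subunits gave 1 higher, Kdm2b (log2 0.77), 1 lower, Yaf2 (log2 -1.42), and 12 not past, with 3 higher and 3 lower when adjusted over the list alone (adjusted p = 0.79, and adjusted p = 0.80 with an estimated correlation). Their median was -0.1 and their mean -0.07 while the set test pointed to higher values. Hox genes, the position genes of the body axis and known PRC2 targets, gave 0 higher, 2 lower and 29 not past of 31, and 0 of the 2 calls held with each array left out. With limma, 0 were higher and 6 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (adjusted p = 0.52, and adjusted p = 0.80 with an estimated correlation).

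Among other imprinted genes in Ezh2-/-, 3 were higher, 10 lower and 20 not past of 33, with 4 higher and 10 lower when adjusted over the list alone (adjusted p = 0.35, and adjusted p = 0.78 with an estimated correlation). Impact fell (log2 -1.45, SE 0.1), as did Sgce (log2 -1.79) and the amino acid transporter gene Slc38a4 (log2 -1.59). Primitive and visceral endoderm markers gave 4 higher, 9 lower and 11 not past of 24, the same when adjusted over the list alone (adjusted p = 0.79, and adjusted p = 0.80 with an estimated correlation). The laminin gene Lama1 rose from 600 ± 35.3 to 3110 ± 138 (log2 2.34, SE 0.1) and Apoe rose (log2 1.09), while the collagen gene Col4a2 fell (log2 -1.62). Primitive streak and mesoderm markers gave 2 higher, 5 lower and 18 not past of 25, with 2 higher and 7 lower when adjusted over the list alone (adjusted p = 0.80, and adjusted p = 0.80 with an estimated correlation). Fgf8, a growth factor of gastrulation, fell from 219 ± 26.2 to 51.1 ± 15.6 (log2 -1.83, SE 0.19), and Isl1 rose (log2 1, same sign at 1 of 2 probe sets). Neural and ectoderm regulators gave 6 higher, 6 lower and 18 not past of 30, the same when adjusted over the list alone (adjusted p = 0.52, and adjusted p = 0.78 with an estimated correlation). Their median was -0.08 and their mean 0.25, with Olig1 and Olig2 among the members, and Nes fell (log2 -1.23). Germline genes gave 2 higher, 4 lower and 11 not past of 17, the same when adjusted over the list alone (adjusted p = 0.35, and adjusted p = 0.80 with an estimated correlation), with Sycp1 higher (log2 0.83) and Hormad1 lower (log2 -1.31).

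**Figure D3:**
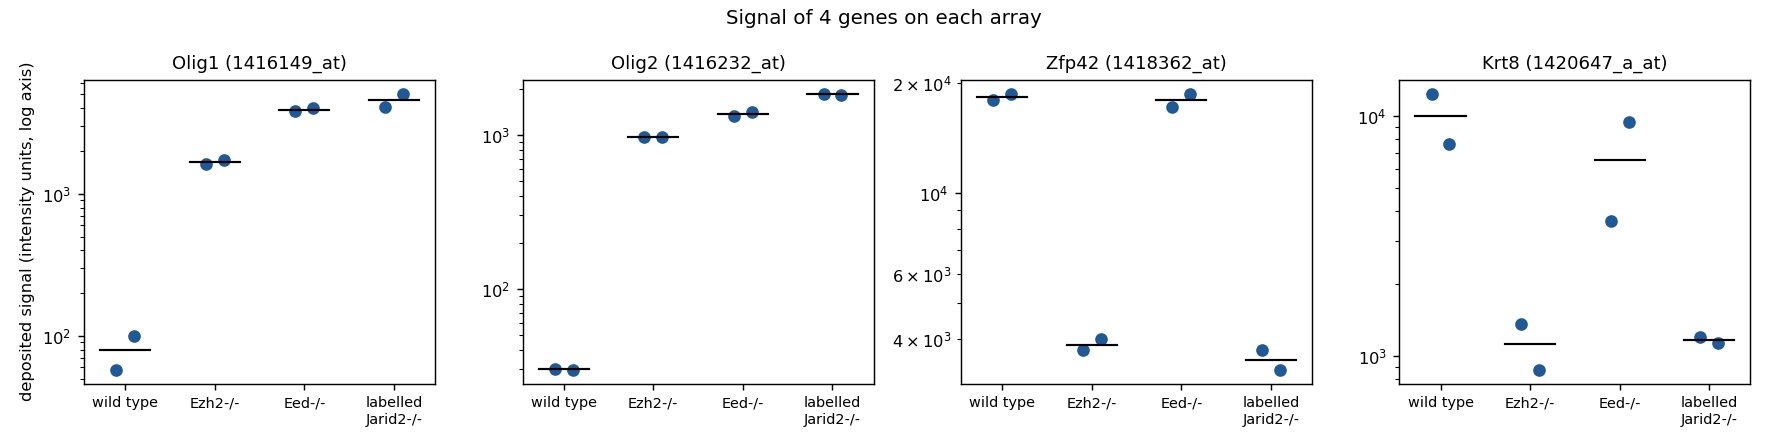
Signal of Olig1, Olig2, Zfp42 and Krt8 (brightest probe set of each gene, intensity on a log axis) in the 8 arrays; points are arrays and bars are means of 2 arrays. Olig2 rose from 30 to 971 in Ezh2-/-, 1360 in Eed-/- and 1830 in the arrays labelled Jarid2-/-, and Zfp42 lay at 18400 in wild type and at 3850 in Ezh2-/-.

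The comparison of Eed-/- with wild type asks the same for EED, without which PRC2 lacks a core subunit. Olig1 rose from 79 ± 30.2 to 3900 ± 135 (log2 5.4, SE 0.19, adjusted p = 2.6e-06) and Olig2 from 30 ± 0.332 to 1360 ± 56.1 (log2 4.9, SE 0.09, adjusted p = 3e-08). Zic1, a neural zinc-finger factor, rose from 64.5 ± 14.6 to 580 ± 27.6, and Sycp1, a protein of meiotic chromosomes, rose from 75.9 ± 0.693 to 574 ± 47.9. The imprinted growth inhibitor Grb10 rose 3.98-fold from 2150 ± 227 to 8600 ± 495 (log2 1.99, SE 0.12, adjusted p = 2.9e-05). Gt(ROSA)26Sor, a locus widely used for transgenes, fell from 875 ± 57 to 17 ± 8.94 (log2 -4.78, SE 0.18, adjusted p = 4.1e-06), while it was 1130 ± 181 in Ezh2-/- and 1080 ± 109 in the arrays labelled Jarid2-/-. The other largest increases were Rgcc (log2 4.08), 2210409E12Rik (log2 3.74), the homeobox gene Rhox6 (log2 3.11) and the proteoglycan gene Srgn (log2 2.79). The other largest decreases besides Meg3 and Rian were Col1a1 (log2 -2.67), Gbp2b (log2 -2.66), Igfbp3 (log2 -2.4), Col1a2 (log2 -2.33) and Dpys (log2 -2.11), with SE between 0.16 and 0.25.

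In Eed-/-, 1743 probe sets were higher and 2470 lower, 4213 in all, and 254 were higher and 145 lower at 2-fold or more. The higher share was 41.4%, and the median over all probe sets was -0.06. The total fell to 2585 without wild type replicate 2, to 2158 without Eed-/- replicate 1 and to 1801 without Eed-/- replicate 2, and it was 2734 among the brighter probe sets.

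Hox genes were higher in Eed-/-, with 11 higher, 1 lower and 19 not past of 31, and the same when adjusted over the list alone (median 0.12, adjusted p = 0.00043, and adjusted p = 0.24 with an estimated correlation). With each array left out in turn 7 of the 11 calls held. Hoxa10 rose from 32.7 ± 3.08 to 281 ± 110 (log2 2.56, SE 0.23, adjusted p = 0.00027), Hoxa11 from 31.4 ± 1.05 to 235 ± 80.5 (log2 2.37, adjusted p = 2e-04) and Hoxd9 from 92.8 ± 6.7 to 385 ± 110 (log2 1.86). With dim probe sets filtered out the Hox list median turned to -0.119. Germline genes gave 6 higher and 11 not past of 17, the same when adjusted over the list alone (median 0.12, adjusted p = 0.00043, and adjusted p = 0.24 with an estimated correlation), among them the RNA-binding genes Dazl (log2 1.4, SE 0.11) and Ddx4 (log2 0.97). Primitive and visceral endoderm markers gave 10 higher, 1 lower and 13 not past of 24, with 11 higher and 2 lower when adjusted over the list alone (median 0.24, adjusted p = 0.00043, and adjusted p = 0.17 with an estimated correlation). Sox7 rose (log2 2.41, SE 0.23), as did Dab2 (log2 1.12) and Lama1 (log2 0.95). Primitive streak and mesoderm markers gave 8 higher, 2 lower and 15 not past of 25, with 9 higher and 2 lower when adjusted over the list alone (median 0.03, adjusted p = 0.026, and adjusted p = 0.24 with an estimated correlation). Most of these mesoderm calls, higher or lower, did not hold with each array left out in turn. Isl1 rose (log2 1.27) with Twist1 (log2 0.96). The germline, endoderm and mesoderm calls ended with dim probe sets filtered out, and the mesoderm call also without wild type replicate 2 (0.139) or Eed-/- replicate 2 (0.051).

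Imprinted genes outside the Dlk1-Dio3 region gave 7 higher, 3 lower and 23 not past of 33 in Eed-/-, with 10 higher and 5 lower when adjusted over the list alone (median 0.03, adjusted p = 0.037, and adjusted p = 0.30 with an estimated correlation). Cdkn1c, a cell cycle inhibitor expressed from the maternal copy, rose from 1170 ± 45.1 to 3800 ± 368 (log2 1.68, SE 0.11, adjusted p = 5e-05), and the Polycomb gene Sfmbt2 rose (log2 1.23). PRC1 subunits gave 3 higher and 11 not past of 14, with 4 higher and 1 lower when adjusted over the list alone (median 0.16, adjusted p = 0.037, and adjusted p = 0.30 with an estimated correlation), led by Bmi1, which rose from 424 ± 81.4 to 1650 ± 11.8 (log2 1.93, SE 0.14). Both set calls ended with dim probe sets filtered out and with the mean over the probe sets of a gene, where the imprinted median was -0.044. Without wild type replicate 2 and without Eed-/- replicate 2 they ended as well, at 0.03 and 0.01 for the imprinted genes and at 0.11 and 0.102 for PRC1. PRC2 subunits gave 1 lower, Eed itself, and 11 not past of 12, with 2 higher and 2 lower when adjusted over the list alone (adjusted p = 0.94, and adjusted p = 0.97 with an estimated correlation).

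The DNA methylation machinery was higher in Eed-/- too, with 6 higher and 8 not past of 14, 11 higher when adjusted over the list alone, and a median of 0.28 (adjusted p = 1.5e-05, and adjusted p = 0.22 with an estimated correlation). Most of the 6 calls did not hold with each array left out in turn. Dppa3, a protein that shields maternal DNA methylation and is also on the germline list, rose from 1890 ± 658 to 5080 ± 156 (log2 1.46, SE 0.19), and Dnmt3a rose (log2 0.78). Pluripotency genes gave 4 higher, 1 lower and 21 not past of 26, with 5 higher and 1 lower when adjusted over the list alone (median 0.17, adjusted p = 0.00043, and adjusted p = 0.17 with an estimated correlation). Tbx3 rose (log2 1.14, SE 0.1, same sign at 1 of 2 probe sets) with Klf4 (log2 0.94), Klf2 fell (log2 -0.46), and Zfp42 stayed at 97.7% of wild type. Fibroblast markers gave 6 lower and 16 not past of 22, with 1 higher and 10 lower when adjusted over the list alone (median -0.29, adjusted p = 0.031, and adjusted p = 0.30 with an estimated correlation), with Vim lower (log2 -1.04). That call ended with dim probe sets filtered out, without wild type replicate 1 (-0.248) and without Eed-/- replicate 1 (-0.149). Neural and ectoderm regulators gave 6 higher, 2 lower and 22 not past of 30, with 6 higher and 4 lower when adjusted over the list alone (adjusted p = 0.18, and adjusted p = 0.30 with an estimated correlation). Their median was -0.02 and their mean 0.41, and Lhx2 rose (log2 1.95). Trophectoderm markers gave 1 higher, 1 lower and 12 not past of 14, the same when adjusted over the list alone (adjusted p = 0.44, and adjusted p = 0.75 with an estimated correlation).

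**Figure D4:**
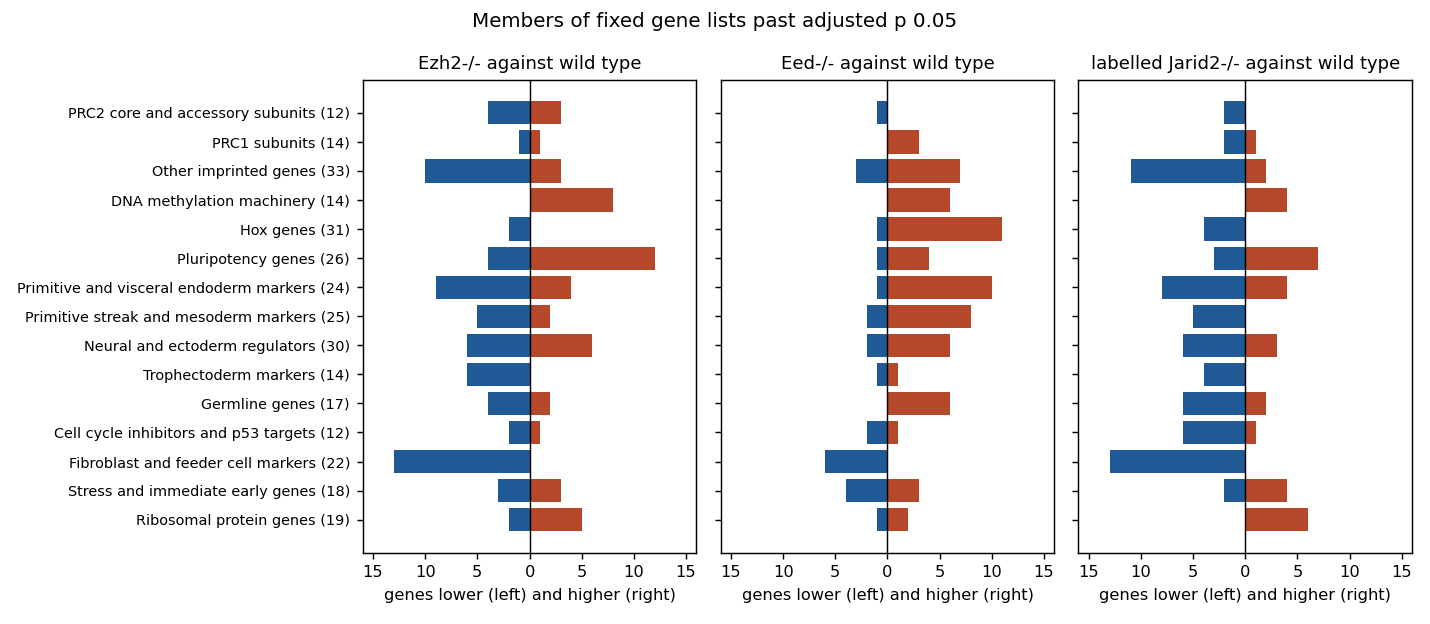
Number of members past an adjusted p of 0.05 in each fixed gene list with at least 10 measured genes, lower to the left and higher to the right, for each mutant against wild type; the number measured is in parentheses. Hox genes had 11 members higher in Eed-/- and 0 in Ezh2-/- and the arrays labelled Jarid2-/-, and fibroblast markers had 13, 6 and 13 members lower.

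The comparison of the arrays labelled Jarid2-/- with wild type asks the same for JARID2. Olig1 rose from 79 ± 30.2 to 4560 ± 717 (log2 5.62, SE 0.19, adjusted p = 1.1e-06) and Olig2 from 30 ± 0.332 to 1830 ± 36.6 (log2 5.33, SE 0.09, adjusted p = 1.4e-08). Zfp42 fell 5.24-fold to 3500 ± 313 (log2 -2.39, SE 0.07, adjusted p = 4.8e-07), 19.1% of wild type. Pmaip1, a cell death gene, rose 4.42-fold from 868 ± 59.6 to 3920 ± 705. Ccnb1ip1, a gene of meiotic crossing over, fell 13.8-fold from 2860 ± 206 to 200 ± 77.2. The other largest increases were Gm6958 (log2 3.8), Rpgrip1 (log2 3.44, same sign at 2 of 4 probe sets), Rgcc (log2 3.13), the ubiquitin-like gene Ubd (log2 2.08) and Wfdc2 (log2 1.98). The other largest decreases besides Meg3 were Gbp2b (log2 -5.54), Col1a1 (log2 -3.67), Acta2 (log2 -3.41), Anxa1 (log2 -3.36), Prss23 (log2 -3.19) and Thbs1 (log2 -3.11), with SE between 0.24 and 0.37.

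In these arrays 1375 probe sets were higher and 3110 lower, 4485 in all, and 177 were higher and 404 lower at 2-fold or more. The higher share was 30.7%, against 48.4% after quantile normalization and 48% with equal array medians. The median over all probe sets was -0.07. Without Jarid2-/- replicate 2 the total was 2728.

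Fibroblast markers were lower in the arrays labelled Jarid2-/-, with 13 lower and 9 not past of 22, 15 lower when adjusted over the list alone, and a median of -0.91 (adjusted p = 1.5e-06, and adjusted p = 0.20 with an estimated correlation). S100a6 fell from 8490 ± 1400 to 2350 ± 274 (log2 -1.84, SE 0.13) and Vim from 10800 ± 1400 to 3050 ± 247 (log2 -1.81, SE 0.14). The DNA methylation machinery gave 4 higher and 10 not past of 14, 5 higher when adjusted over the list alone, and a median of 0.16 (adjusted p = 0.00025, and adjusted p = 0.26 with an estimated correlation). Dnmt3b rose to 13900 ± 597 (log2 0.51, SE 0.05, adjusted p = 0.00037), with Dnmt3a (log2 0.83) and Dppa3 (log2 1.07). Pluripotency genes gave 7 higher, 3 lower and 16 not past of 26, with 8 higher and 3 lower when adjusted over the list alone (median 0.13, adjusted p = 0.0014, and adjusted p = 0.20 with an estimated correlation). Nr0b1 rose from 4290 ± 392 to 7970 ± 156 (log2 0.89, SE 0.1), with Klf5 (log2 0.7) and Tbx3 (log2 0.84, same sign at 1 of 2 probe sets).

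Developmental and Polycomb lists did not pass as sets in the arrays labelled Jarid2-/-. Hox genes gave 0 higher, 4 lower and 27 not past of 31, the same when adjusted over the list alone, and with limma 0 were higher and 8 lower at an unadjusted p under 0.05 (adjusted p = 0.12, and adjusted p = 0.48 with an estimated correlation). With each array left out in turn 1 of the 4 calls held. Hoxb5 fell from 134 ± 5.93 to 87.7 ± 3.39 (log2 -0.54, SE 0.1), both within the range of the negative controls. Other imprinted genes gave 2 higher, 11 lower and 20 not past of 33, the same when adjusted over the list alone (adjusted p = 0.12, and adjusted p = 0.48 with an estimated correlation), with Ndn lower (1340 ± 104 to 562 ± 50.8, log2 -1.23, SE 0.11) and Grb10 higher (log2 1.01). Germline genes gave 2 higher, 6 lower and 9 not past of 17, with 2 higher and 7 lower when adjusted over the list alone (adjusted p = 0.10, and adjusted p = 0.48 with an estimated correlation), and Stk31 fell (log2 -1.55). Primitive streak and mesoderm markers gave 5 lower and 20 not past of 25, with 8 lower when adjusted over the list alone (adjusted p = 0.13, and adjusted p = 0.41 with an estimated correlation), and Fgf8 fell (log2 -2, SE 0.19). Primitive and visceral endoderm markers gave 4 higher, 8 lower and 12 not past of 24, with 5 higher and 8 lower when adjusted over the list alone (adjusted p = 0.83, and adjusted p = 0.85 with an estimated correlation); Lama1 rose (log2 1.11) and Sparc fell (log2 -1.21). Neural and ectoderm regulators gave 3 higher, 6 lower and 21 not past of 30, the same when adjusted over the list alone (adjusted p = 0.94, and adjusted p = 0.96 with an estimated correlation). Their median was -0.17 and their mean 0.17, and Neurod1 fell (log2 -1.4). Trophectoderm markers gave 4 lower and 10 not past of 14, the same when adjusted over the list alone (adjusted p = 0.069, and adjusted p = 0.48 with an estimated correlation), including Krt8 (10000 ± 3360 to 1170 ± 47.1, log2 -3.05, SE 0.4). PRC1 subunits gave 1 higher, 2 lower and 11 not past of 14, with 1 higher and 3 lower when adjusted over the list alone (adjusted p = 0.94, and adjusted p = 0.96 with an estimated correlation). PRC2 subunits gave 2 lower and 10 not past of 12, with 1 higher and 3 lower when adjusted over the list alone (adjusted p = 0.93, and adjusted p = 0.96 with an estimated correlation).

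Genes changed in the same direction in all 3 mutants were compared next. The 3 mutants shared 415 probe sets higher and 1009 lower than wild type. Olig1 and Olig2 led the shared increases, followed by Rpgrip1, the glutathione peroxidase gene Gpx2, Pmaip1, the kinase gene Ptk2b, Wfdc2 and Niban1. Gpx2 rose from 315 ± 34.7 to 3520 ± 1.73 in Ezh2-/- (log2 3.42, SE 0.13), to 1240 ± 120 in Eed-/- (log2 1.92) and to 654 ± 95.6 in the arrays labelled Jarid2-/- (log2 1.01). Ptk2b rose by 2.26, 1.55 and 1.41 on the log2 scale in the same order, Pmaip1 by 1.59, 2.47 and 2.14, and Niban1 by 2.1, 1.32 and 1.4. Gbp2b, Meg3, Col1a1, Rian, Igfbp3, Krt19, Acta1 and Acta2 led the shared decreases. Igfbp3, which binds insulin-like growth factors, was 4680 ± 2150 in wild type and 359 ± 36.7, 828 ± 4.98 and 546 ± 1.75 in the mutants (log2 -3.57, -2.4 and -2.98, SE 0.25). Krt19 changed by -3.8, -1.87 and -2.98 (SE 0.3). The Acta2 call in Eed-/- (log2 -1.3) ended without wild type replicate 1 (-1.067) or Eed-/- replicate 1 (-0.751).

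Across 12393 genes the log2 changes of Ezh2-/- and the arrays labelled Jarid2-/- correlated with Pearson's r of 0.65, where 100 simulations of unchanged groups against the same wild type arrays gave 0.499. For Ezh2-/- and Eed-/- r was 0.505 against 0.5 simulated, and for Eed-/- and the arrays labelled Jarid2-/- 0.497 against 0.5. Unchanged groups of equal size against shared wild type arrays give r near 0.5 whatever their spread. An r near 0.5 is therefore no sign that mutants are unlike. The covariance was 0.0867 for Ezh2-/- and Eed-/-, 0.1191 for Ezh2-/- and the arrays labelled Jarid2-/-, and 0.0703 for the remaining pair. Simulations gave 0.0083 for each pair, which left differences of 0.0784, 0.1108 and 0.062. Genes are not independent replicates, and these are 3 pairs of the same family without a p. Among genes, 456 were higher in both Ezh2-/- and Eed-/- where independence gives 94.1, and 820 were lower in both where it gives 244.3. The overlaps were 396 higher (71.5) and 1057 lower (314.2) for Ezh2-/- and the arrays labelled Jarid2-/-, and 312 higher (58.1) and 714 lower (193.7) for Eed-/- and the arrays labelled Jarid2-/-. All 3 comparisons share the 2 wild type arrays, so independence is not the value that unchanged groups would give for these overlaps. Genes of the same sign made up 71.4%, 71.8% and 70.7% in the order of the overlaps, against 66.7%, 66.6% and 66.7% simulated. When each mutant of a pair was set against a separate wild type array, r was 0.409 and 0.372 for Ezh2-/- and Eed-/-, 0.643 and 0.434 for Ezh2-/- and the arrays labelled Jarid2-/-, and 0.455 and 0.278 for the remaining pair, 1 value for each way round, a test chosen after seeing the data. In these fits 319 and 280 genes were higher in both Ezh2-/- and Eed-/- (60.5 and 69.1 by independence) and 499 and 429 lower in both (140.6 and 127.8). For Ezh2-/- and the arrays labelled Jarid2-/- 306 and 252 were higher (38.9 and 71.8) and 660 and 626 lower (160.3 and 236.6), and for the remaining pair 206 and 206 were higher (33.2 and 53.7) and 364 and 359 lower (81.4 and 132.2). Any difference of the wild type line from all mutants stays in these overlaps.

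Whole chromosomes also moved together, with genes placed by the mouse assembly GRCm38.p6. Over the 339 genes of chromosome 8 with a mean signal above 500, the median log2 difference from wild type was -0.31 in Ezh2-/-, -0.34 in Eed-/- and -0.3 in the arrays labelled Jarid2-/- (set test adjusted p = 2.4e-06, 5.5e-14 and 1.2e-07). Medians in this paragraph are of bright genes, while each set test covers all genes of a chromosome, such as 645 on chromosome 8 with medians of -0.232, -0.287 and -0.223. Over 311 genes of chromosome 1 it was -0.22, -0.17 and -0.23, and over 206 genes of chromosome 19 it was -0.2, -0.18 and -0.19 (adjusted p of at most 0.0022 for both). Chromosome 11 was lower in Ezh2-/- (-0.14, adjusted p = 0.023) and Eed-/- (-0.13, adjusted p = 0.0019) and not past in the arrays labelled Jarid2-/- (-0.07, adjusted p = 0.4), and the Ezh2-/- call ended without wild type replicate 1 (-0.126). Chromosome 6 was lower in the arrays labelled Jarid2-/- than in wild type (-0.12, adjusted p = 0.0052), Eed-/- (-0.23, adjusted p = 0.013) and Ezh2-/- (-0.16, adjusted p = 0.021). Its 4 equal parts in gene order were at -0.152, -0.53, -0.04 and 0 against wild type, so this shift did not cover the whole chromosome. Further calls against wild type were chromosomes 7 (0.08, adjusted p = 0.039) and X (-0.17, adjusted p = 0.023) in Ezh2-/-, 12 in Eed-/- (0.06, adjusted p = 0.0067), 17 in the arrays labelled Jarid2-/- (0.07, adjusted p = 0.0054), and Y with 8 genes in Ezh2-/- and the arrays labelled Jarid2-/- (adjusted p = 0.0058 and 0.023). Over all genes the medians were -0.013 for chromosome 7 in Ezh2-/-, 0.016 for 12 in Eed-/- and 0.006 for 17 in the arrays labelled Jarid2-/-. The median over all probe sets was -0.069, -0.06 and -0.073 in the same mutants. The set test compares a chromosome with the other genes, so these 3 calls are relative to a median below 0. The chromosome 7 call ended without wild type replicate 1 (0.072) or Ezh2-/- replicate 2 (0.073), and the chromosome X call without wild type replicate 1 (-0.2). The chromosome 12 median in Eed-/- was 0.026 without wild type replicate 1, 0.09 without Eed-/- replicate 1 and 0.037 without Eed-/- replicate 2. With an estimated correlation the calls held for chromosomes 8 and 11 in Eed-/- (adjusted p = 0.047 for each) and ended for chromosome 8 in the other 2 mutants (adjusted p = 0.13 and 0.096) and for all others named here. A small decrease of a gene on these chromosomes is therefore not separate from that shift.

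**Figure D5:**
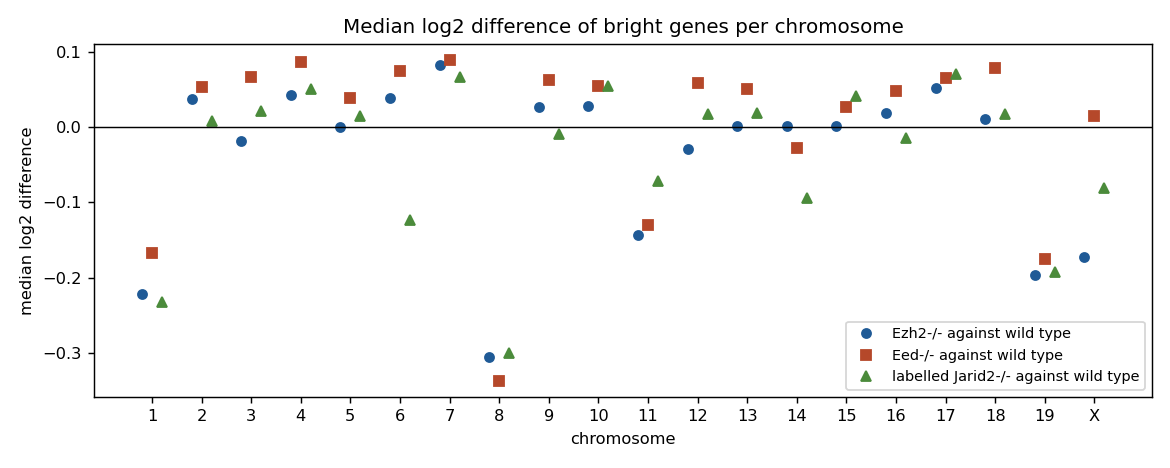
Median log2 difference from wild type of genes with a mean signal above 500, per chromosome (horizontal axis), for each mutant (symbols). Chromosomes 8, 1 and 19 lay below 0 in all 3 mutants, at -0.31, -0.34 and -0.3 for chromosome 8.

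Direct comparisons between mutants ask where the mutants differed from each other. Between Ezh2-/- and Eed-/-, Cd99, a cell surface glycoprotein gene, was 44.8 ± 5.38 and 1840 ± 12.3 (log2 -4.93, SE 0.13, adjusted p = 1.2e-07), and Rhox6 was 68.7 ± 4.4 and 1370 ± 493 (log2 -3.98, SE 0.24). The carbonyl reductase gene Cbr3 was higher in Ezh2-/-, 5640 ± 679 against 1080 ± 115 (log2 2.37, SE 0.13). The remaining largest differences were Gt(ROSA)26Sor (log2 5.13), Gm6958 (log2 4.88), Tmem267 (log2 2.52) and Erdr1 (log2 2.05) upward and Eif2s3y (log2 -6.08), Uty (log2 -4.08) and Glrx (log2 -3.85) downward. In all 1285 probe sets were higher and 2513 lower in Ezh2-/-, 3798 together, with a higher share of 33.8%, against 45.4% after quantile normalization and 55% with equal array medians. The total was 1590 without Ezh2-/- replicate 1, 1373 without Ezh2-/- replicate 2, 1632 without Eed-/- replicate 2 and 5728 from the 4 arrays compared alone.

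Several developmental lists were lower in Ezh2-/- than in Eed-/-. Germline genes gave 10 lower and 7 not past of 17, 12 lower when adjusted over the list alone (adjusted p = 2.1e-07, and adjusted p = 0.15 with an estimated correlation). Hox genes gave 10 lower and 21 not past of 31, 12 lower when adjusted over the list alone (adjusted p = 0.00014, and adjusted p = 0.16 with an estimated correlation). Other imprinted genes gave 1 higher, 13 lower and 19 not past of 33, with 1 higher and 14 lower when adjusted over the list alone (adjusted p = 0.00091, and adjusted p = 0.16 with an estimated correlation). Primitive and visceral endoderm markers gave 3 higher, 13 lower and 8 not past of 24, the same when adjusted over the list alone (adjusted p = 0.0033, and adjusted p = 0.15 with an estimated correlation). The set test also called primitive streak and mesoderm markers (8 lower of 25, adjusted p = 0.0048), trophectoderm markers (6 lower of 14, adjusted p = 0.039) and fibroblast markers (9 lower of 22, adjusted p = 0.0017), with adjusted p = 0.15, 0.44 and 0.16 with an estimated correlation. Neural and ectoderm regulators did not pass, with 3 higher, 10 lower and 17 not past of 30, and 5 higher and 10 lower when adjusted over the list alone (adjusted p = 0.30, and adjusted p = 0.44 with an estimated correlation). Alternatives were not run for lists between mutants.

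Between the arrays labelled Jarid2-/- and Eed-/-, the imprinted growth factor gene Igf2 was 252 ± 35.7 and 4510 ± 3100 (log2 -3.89, SE 0.41, adjusted p = 0.00038), and the imprinted zinc-finger gene Plagl1 was 539 ± 64.7 and 6020 ± 2420 (log2 -3.39, SE 0.23). Ntn1, an axon guidance gene, was higher in the arrays labelled Jarid2-/-, 3500 ± 493 against 820 ± 55.1 (log2 2.07, SE 0.11). The remaining largest differences were Gt(ROSA)26Sor (log2 5.08), Gm6958 (log2 3.97), Trim34a (log2 2.14, same sign at 1 of 2 probe sets) and Slc23a1 (log2 1.98) upward and 2210409E12Rik (log2 -3.61), Crxos (log2 -3.32) and Pmp22 (log2 -3.11) downward. In all 1129 probe sets were higher and 2239 lower, 3368 together, with a higher share of 33.5%, against 45.7% after quantile normalization and 52.1% with equal array medians. Without Eed-/- replicate 2 the total was 1360 and without Jarid2-/- replicate 2 it was 2216. Hox genes gave 14 lower and 17 not past of 31, 16 lower when adjusted over the list alone (adjusted p = 9.2e-06, and adjusted p = 0.12 with an estimated correlation). Germline genes gave 1 higher, 9 lower and 7 not past of 17, the same when adjusted over the list alone (adjusted p = 5.8e-07, and adjusted p = 0.12 with an estimated correlation). Also lower as sets were other imprinted genes (12 lower of 33, adjusted p = 0.00011), endoderm markers (11 lower of 24, adjusted p = 0.00027), mesoderm markers (13 lower of 25, adjusted p = 0.00011) and fibroblast markers (10 lower of 22, adjusted p = 9.9e-06), with adjusted p = 0.12, 0.11, 0.11 and 0.12 with an estimated correlation. Neural regulators (6 lower of 30, adjusted p = 0.076) and trophectoderm markers (4 lower of 14, adjusted p = 0.12) did not pass, with adjusted p = 0.21 and 0.50 with an estimated correlation.

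Between the arrays labelled Jarid2-/- and Ezh2-/-, Dpys was 2070 ± 412 and 33.6 ± 4.56 (log2 5.38, SE 0.16, adjusted p = 5e-07), with the same sign at 1 of 3 probe sets, and the ribosomal protein paralog gene Rpl39l was 4960 ± 725 and 442 ± 22.6 (log2 3.43, SE 0.11). Abca1, a cholesterol exporter gene, was lower in the arrays labelled Jarid2-/-, 199 ± 62.1 against 2430 ± 35.7 (log2 -3.54, SE 0.19), and the homeobox gene Meis1 was 86 ± 20.8 against 682 ± 0.332 (log2 -2.79, SE 0.14). The remaining largest differences were Eif2s3y (log2 3.99), Cd99 (log2 3.83) and Fxyd6 (log2 3.45) upward and 2210409E12Rik (log2 -4.06), Apoa2 (log2 -3.27) and Tchh (log2 -2.89) downward. In all 1757 probe sets were higher and 1647 lower, 3404 together, with a higher share of 51.6%. The total was 1218 without Ezh2-/- replicate 1, 1124 without Ezh2-/- replicate 2 and 1543 without Jarid2-/- replicate 2. Developmental lists did not pass here, and the Hox genes gave 1 lower and 30 not past of 31, the same when adjusted over the list alone (adjusted p = 0.68, and adjusted p = 0.85 with an estimated correlation).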

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

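All tests of explanations in this part were chosen after the results were seen, while the direct comparisons between mutants were planned.

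Over 12393 genes, 96 were called in opposite directions in Ezh2-/- and Eed-/-, 94 in Ezh2-/- and the arrays labelled Jarid2-/-, and 99 in Eed-/- and the arrays labelled Jarid2-/-. Described here are those among the genes that the naming rules and the fixed lists had picked, apart from the 3 targeted genes, where the direct comparison of the mutants passed as well, which gave 37 differences with adjusted p of at most 0.0014 and SE of at most 0.41. Values are log2 differences between the 2 mutants, with 2 arrays in each group. Of these, 14 were between Ezh2-/- and Eed-/-. The Y-linked translation factor gene Eif2s3y differed by -6.08, the surface glycoprotein gene Cd99 by -4.93, Rhox6 by -3.98, the glutaredoxin gene Glrx by -3.85 and Crxos by -3.69. Imprinted genes among them were Igf2 at -3.11, Plagl1 at -2.66 and Sfmbt2 at -1.77. Developmental genes were Hoxd8 at -2.49, Col4a2 at -2.31, Dab2 at -1.67 and Gata2 at -1.27. Trim34a was at 1.33 and Erdr1 at 2.05. In Ezh2-/- the signals of Eif2s3y, Cd99, Rhox6, Crxos, Dab2 and Hoxd8 lay within or below the range of the negative controls, as did those of Rhox6 and Hoxd8 in wild type, so these sizes are not exact. The call of Hoxd8 as lower in Ezh2-/- ended without wild type replicate 1 (-0.691) and without Ezh2-/- replicate 1 (-0.617).

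Between the arrays labelled Jarid2-/- and Ezh2-/- there were 5 such genes, Abca1 at -3.54, Ddx4 at -1.06, Sfmbt2 at 1.63, Rhox6 at 2.24 and Cd99 at 3.83. Another 18 were between the arrays labelled Jarid2-/- and Eed-/-. The imprinted genes in this set were Igf2 at -3.89, Plagl1 at -3.39, Cdkn1c at -2.28 and Ndn at -1.87. Germline genes were Stk31 at -2.24, Tex11 at -1.82 and Ddx4 at -1.62. Other differences were Crxos at -3.32, Col4a2 at -2.12, Eif2s3y at -2.09, Glrx at -1.93, Dab2 at -1.88, Hoxc13 at -1.87, Hoxc4 at -1.53 and Cbx2 at -0.82. Erdr1 was at 1.92, Ntn1 at 2.07 and Trim34a at 2.14. Hoxc13, Hoxc4 and Tex11 lay within the range of the negative controls in wild type and in the arrays labelled Jarid2-/-, Trim34a in wild type and Eed-/-, and Crxos, Dab2 and Stk31 in the arrays labelled Jarid2-/-. The call of Eif2s3y as higher in Eed-/- ended without either wild type array (0.479 without replicate 1, 0.426 without replicate 2) or either Eed-/- array (0.403 without replicate 1, 0.502 without replicate 2). The call of Hoxc13 as lower in the arrays labelled Jarid2-/- ended without wild type replicate 2 (-0.487) and without replicate 1 of these arrays (-0.599), and so did that of Hoxc4 (-0.684 and -0.711). The call of Cbx2 as lower there ended without wild type replicate 1 (-0.364) or 2 (-0.402), Ezh2-/- replicate 1 or 2 (-0.383 for each), or replicate 1 (-0.353) or 2 (-0.413) of these arrays, and its call as higher in Eed-/- ended without wild type replicate 2 (0.415) and without Eed-/- replicate 2 (0.309).

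Meg3 and Rian fell beside fibroblast markers, and wild type cultures with more fibroblast-like or feeder cells could give both. In Eed-/- 0 of 8 markers above 500 in wild type fell as far as Rian (-2.37), with Col1a2 close to it at -2.33 and the others at -1.3 or above, while Col1a1, at 490 in wild type, fell further at -2.67; Tagln (3000 and 5667), Acta2 (932 and 1999) and the other markers were higher in replicate 2 than in replicate 1 of Eed-/-, where Meg3 (1475 and 1202.4) and Rian (202.7 and 181.3) were not. In Ezh2-/- 0 of 8 fell as far as Rian as read (-4.06), but Rian lay within the range of the negative controls and cannot be ranked. Thbs1 (97 and 81, log2 -3.5) lay within that range too, so its fall cannot be ranked either. Tagln had the largest fall of the 8 as read (log2 -3.69) and stayed above the controls. Meg3, set against the highest control, fell at least 52.8-fold, further than Tagln. In the arrays labelled Jarid2-/- 3 of 8 fell as far as Rian (-2.63) as read, the lowest being Acta2 at -3.41. The other members of the 3, Thbs1 (113 and 129) and Col1a2 (137 and 128), lay within the range of the negative controls there. Rian itself (167.3 and 148.4) was barely above the highest control, so this ranking is not firm either. How much of each marker, and of the remaining Meg3 and Rian, the stem cells make is not known from these arrays. Also, 2 arrays are too few to follow markers and locus together, and genotype and cell line coincide. Fewer such cells, another difference between the lines and a direct effect on the locus can therefore not be told apart.

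Ezh2 was lower and Jarid2 was not lower in the arrays labelled Jarid2-/-. RNA of Ezh2-/- cells in these arrays would need a share of 43.3% to give the Ezh2 signal, yet 17 of 38 genes raised in Ezh2-/- stayed below that share of their Ezh2-/- signal, such as Abca1 at 8.2% and Apoa2 at 9.5%, which argues against it. A lower copy number of the part of chromosome 6 that holds Ezh2 may underlie the lower signal, as the 20 bright genes on each side had a median of -0.504 (standard error 0.078) against -0.66 for Ezh2, and the 4 equal parts of that chromosome in gene order were at -0.152, -0.53, -0.04 and 0. The standard error of 0.078 treats these neighbouring genes as independent and does not measure the spread between arrays or cultures. Jarid2 probe sets outside the deleted part of the gene would read as in wild type or above, and the brightest was at 0.25, which stays open because the deleted part and the probe positions are not used here. An effect of JARID2 on Ezh2 expression was not tested.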

How the results depend on the processing

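The fits without the 2 arrays labelled Jarid2-/-, the separate wild type arrays and all alternatives of the chromosome medians were chosen after seeing the data, and the other alternatives were planned.

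Of 259 calls of named genes, 228 held under every processing alternative and 31 ended under at least 1, with 0 reversed, and 215 held with each array left out in turn while 44 ended. Of 334 calls of list members against wild type, 202 held with each array left out and 132 ended. Of 19 gene list calls, 0 held with an estimated correlation, which gave 0 lists past the threshold in each mutant against 5, 9 and 5. Leaving that alternative aside, 8 held, 10 ended and 1 reversed, and 12 held with each array left out. Meg3, Rian and the loss of Ezh2 and Eed in their own mutants kept direction and call throughout.

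With dim probe sets filtered out, the Eed-/- total was 2734, the lists past the threshold were 3 in Ezh2-/- and 2 in Eed-/-, r between Ezh2-/- and the arrays labelled Jarid2-/- was 0.602, and the Hox genes in Eed-/- reversed to a median of -0.119. The filter removed the dimmer Hox genes and left the log2 difference of each remaining gene as it was, so the median changed because members were dropped. Jarid2 in the arrays labelled Jarid2-/- passed under quantile normalization (0.272) and equal array medians (0.315). With the replicate number as a block, Jarid2 (0.246) in those arrays and Dlk1 in Ezh2-/- (-0.312) passed. From only the 4 arrays compared, the totals were 2469 in Eed-/-, 2544 in the arrays labelled Jarid2-/- and 5728 between Ezh2-/- and Eed-/-. The cause was not tested. A 2-fold limit left 862 in Ezh2-/-, 399 in Eed-/-, 581 in the arrays labelled Jarid2-/-, 749 between Ezh2-/- and Eed-/-, 577 between the arrays labelled Jarid2-/- and Eed-/-, and 492 between the arrays labelled Jarid2-/- and Ezh2-/-, because the limit removes smaller changes.

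With an estimated correlation the chromosome medians of bright genes were unchanged and the calls ended, for chromosomes 8, 1, 19, 11, 7 and X in Ezh2-/- (-0.306, -0.222, -0.196, -0.143, 0.082 and -0.173), for 1, 19 and 12 in Eed-/- (-0.167, -0.175 and 0.059) and for 8, 1, 19, 6 and 17 in the arrays labelled Jarid2-/- (-0.3, -0.232, -0.193, -0.124 and 0.071). Whether a larger correlation ended them was not tested. Among the gene lists, endoderm markers in Eed-/- lost their camera call although their estimated correlation, -0.015, lay below the preset 0.01. Chromosome 7 in the arrays labelled Jarid2-/- passed under quantile normalization (0.097) and, like chromosome 17 in Ezh2-/- (0.052), with dim probe sets filtered out (0.067). With each array left out, the Ezh2-/- medians ranged from -0.156 to -0.126 for chromosome 11, 0.072 to 0.089 for 7, 0.042 to 0.06 for 17 and -0.2 to -0.173 for X, and those of chromosome 12 from 0.026 to 0.09 in Eed-/- and from -0.002 to 0.039 in the arrays labelled Jarid2-/-. With a separate wild type array for each mutant, r was 0.409 and 0.372 for Ezh2-/- and Eed-/-, and 0.434 and 0.278 the second way round for the arrays labelled Jarid2-/- with Ezh2-/- and with Eed-/-.

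With each array left out in turn, where the lone array left in a group is assumed to vary like the others, totals ranged from 2655 to 6167 in Ezh2-/-, 1801 to 4283 in Eed-/- and 2728 to 4149 in the arrays labelled Jarid2-/-. Between mutants they ranged from 1373 to 4446 for Ezh2-/- and Eed-/-, 1360 to 4045 for the arrays labelled Jarid2-/- and Eed-/-, and 1124 to 4211 for the arrays labelled Jarid2-/- and Ezh2-/-. Lists past the threshold ranged from 3 to 6 in Ezh2-/-, Dlk1 in the arrays labelled Jarid2-/- from -0.666 to -0.467, and Jarid2 there from 0.131 to 0.361. Totals fell when an array of a compared group was left out, and without either array of a group outside the comparison some rose and others fell, a difference whose cause was not tested.

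Without the 2 arrays labelled Jarid2-/- the totals were 6162 in Ezh2-/-, 4275 in Eed-/- and 3952 between them. The value table planned as an alternative is the input used here, and the filter on present calls was not run for lack of calls. Signals near the negative controls, which read 23.76 to 147.91, limit what can be said of dim genes such as Dlk1 and of Meg3, Rian, Eif2s3y and Uty in Ezh2-/-.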

Other observations

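The chromosome tests below were chosen after the medians were seen, while the gene lists and the chromosome medians were planned.

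Stress and immediate early genes did not pass as a set in any mutant. Atf4, a transcription factor of the amino acid response, went from 5210 ± 415 to 9420 ± 322 in the arrays labelled Jarid2-/- (SD, n = 2 arrays, log2 0.86, SE 0.07, adjusted p = 9.3e-05), and its targets Chac1 and Trib3 rose by 1.14 and 1.02 on the log2 scale. The 18 genes of the list gave 4 higher, 2 lower and 12 not past, with 5 higher and 4 lower when adjusted over the list alone (adjusted p = 0.22, and adjusted p = 0.47 with an estimated correlation). The list median was -0.07 and its mean 0.02. In Ezh2-/- Atf4 rose (log2 0.75) with the heat shock gene Hspb1 (log2 0.59), and the list gave 3 higher, 3 lower and 12 not past (adjusted p = 0.79, and adjusted p = 0.80 with an estimated correlation), its median -0.17 below 0 while the set test pointed upward. In Eed-/- Chac1 rose (log2 0.94) and the immediate early gene Ier2 fell (log2 -0.77), among 3 higher, 4 lower and 11 not past (adjusted p = 0.74, and adjusted p = 0.75 with an estimated correlation), its median -0.07 and mean -0.02 below 0 while the set test pointed upward. When adjusted over the list alone, 5 were higher and 5 lower in Ezh2-/- and 3 higher and 4 lower in Eed-/-.

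Ribosomal protein genes were higher in the arrays labelled Jarid2-/-, with 6 higher and 13 not past of 19, 7 higher and 1 lower when adjusted over the list alone, and a median of 0.04 (adjusted p = 0.0032, and adjusted p = 0.26 with an estimated correlation). The call ended under quantile normalization (0.027). Rps6 rose from 1250 ± 161 to 2050 ± 72.5 (log2 0.71, SE 0.1) with the same sign at 1 of 2 probe sets, and in Ezh2-/- it rose to 3320 ± 32.9 (log2 1.4). The list gave 5 higher, 2 lower and 12 not past in Ezh2-/-, the same when adjusted over the list alone (adjusted p = 0.083, and adjusted p = 0.57 with an estimated correlation). In Eed-/- it gave 2 higher, 1 lower and 16 not past, with 2 higher when adjusted over the list alone (adjusted p = 0.059, and adjusted p = 0.30 with an estimated correlation).

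Cell cycle inhibitors and p53 targets did not pass as a set in any mutant, and in the arrays labelled Jarid2-/- there were 1 higher, 6 lower and 5 not past of 12, and 2 higher and 6 lower when adjusted over the list alone (adjusted p = 0.27, and adjusted p = 0.56 with an estimated correlation). The p53 target Phlda3 fell from 3150 ± 30.8 to 1900 ± 361 (log2 -0.74, SE 0.13). In Ezh2-/- 1 was higher, 2 lower and 9 not past, with 1 higher and 4 lower when adjusted over the list alone (adjusted p = 0.76, and adjusted p = 0.80 with an estimated correlation), and Cdkn1a fell (log2 -1.37, SE 0.26). In Eed-/- the counts were 1 higher, 2 lower and 9 not past, the same when adjusted over the list alone (adjusted p = 0.96, and adjusted p = 0.97 with an estimated correlation), its median at -0.17 and its mean at 0.05. Of 6 genes of the 2-cell-like state, limma placed 1 lower in Ezh2-/- (2 lower at an unadjusted p under 0.05) and 0 in Eed-/- (0 unadjusted) and in the arrays labelled Jarid2-/- (1 lower unadjusted). Adjusted over the list alone these counts were the same (adjusted p = 0.79, 0.86 and 0.83, and adjusted p = 0.80, 0.87 and 0.85 with an estimated correlation).

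Y-linked genes with Xist gave 3 lower and 1 not past of 4 in Ezh2-/-, the same when adjusted over the list alone (median -2.51, adjusted p = 0.0045, and adjusted p = 0.20 with an estimated correlation). In the arrays labelled Jarid2-/- they also gave 3 lower and 1 not past, the same when adjusted over the list alone (median -1.04, adjusted p = 0.036, and adjusted p = 0.26 with an estimated correlation), with Eif2s3y at 31.4% and Uty, within the range of the negative controls, at no more than 36.5% of wild type. This set call ended with a pseudocount of 1 (-1.099), without wild type replicate 2 (-1.017) and without Jarid2-/- replicate 2 (-0.868). In Eed-/- 1 was higher, 1 lower and 2 not past, the same when adjusted over the list alone (adjusted p = 0.86, and adjusted p = 0.87 with an estimated correlation), and Eif2s3y was at 137.3% and Uty at 102.7% of wild type.

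Genes of chromosomes 8, 1 and 19 were lower in all 3 mutants than in wild type by camera at the preset correlation. With an estimated correlation only chromosome 8 in Eed-/- passed among them (camera adjusted p = 0.047). A scaling of whole arrays moves all chromosomes alike. The chromosome 8 median lay below that of the other chromosomes in each mutant, with a difference of -0.302 in the mutant nearest 0. Such scaling alone would not give that difference. Of bright chromosome 8 genes 83.2% were lower in Ezh2-/-, the lowest share of the 3 mutants, against 50.2% on other chromosomes. Chromosome 8 was picked for its low median, so neither check is independent of that choice. They show only that the shift was not limited to a few genes. A copy number difference between the wild type line and the 3 mutant lines may underlie it, as each of 4 equal parts of these chromosomes in gene order was lower in every mutant, the highest median of a part being -0.136, while whole-chromosome medians between mutants reached at most -0.081 on chromosome 1. It stays open, since medians of parts between Ezh2-/- and Eed-/- reached -0.106 on chromosome 1 and 0.101 and -0.104 on chromosome 19. Genotype and cell line coincide, so an effect of PRC2 loss was not tested and stays open. A shared loss in the mutants would shift these genes in the same direction as a gain in wild type, and which of them applies was not tested.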
